A study of Papio hamadryas with 11 samples.

How the data were processed

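Small RNA was sequenced from the livers of 11 baboon fetuses (Papio hamadryas) at 0.9 of gestation. The mothers of 6 fetuses were controls (3 female and 3 male fetuses) and the mothers of 5 were obese (3 female and 2 male fetuses). Per the labels' protocols, RNA was extracted with a Qiagen miRNeasy kit, libraries were made with the Illumina TruSeq small RNA kit, and 12 libraries were pooled per lane for 36 cycles of single-end sequencing on a Genome Analyzer IIx. Fetuses are named below by maternal group and the replicate number in the labels. The labels list separate samples and do not number the animals, so p-values measure the spread between these samples.

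The deposited workbook, named for miRDeep2, held a table of known miRNAs and a table of predicted miRNAs. The first held whole-number read counts per mature miRNA and precursor in 11 columns, which the authors deposited without scaling. It also held, per the file headers, normalised columns, a signal that the values show to be reads scaled to the library's count total. The submitters' processing notes name the human build hg18, and the miRNA names are those of human miRBase, so baboon reads were counted against human sequences. The miRDeep2 version, aligner settings and mismatch limits are not given in the sources used here. The 2234 rows of the known table appear again below themselves, giving 4468 rows, so that each deposited normalised column sums to 2 times the scale of its library. Every row was used 1 time. Where a mature name stood on several precursors (313 further rows), the row with the highest total was kept, because a read that fits several precursors may be counted at each. This left 1921 mature names, of which 645 had reads. Mature sequences were not used here, so members of families with near-identical sequences (let-7 and miR-98, miR-378, miR-199, miR-30) are reported as uncertain in how reads were shared among them.

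In the table of predicted miRNAs, the raw-count columns were an exact copy of the leading 470 rows of the known table and were not used. Its normalised columns were deposited as RPM, scaled to that table's own total. Within 0.0051 RPM, 100% of these values in every library came out as whole reads of totals between 264456 and 830728. A count model had been chosen for this table. Because its usable unit was RPM, limma on log2(RPM + 1) was used, after division by the table's own TMM factors, and count models on the recovered reads became alternatives. The TMM division was chosen after the result without it had been seen (16 entries past the threshold, against 17 with it). It was added because the undivided test made false calls on simulated data with abundant entries changed, and the number of simulated draws was raised from 1 to 5 at the same point. Over the 5 draws, false calls made up a median of 10.3% of calls without the division and 5.26% with it. A column of pooled read counts in the workbook was 15.1 times the sum of the 11 libraries and was not used.

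Differences were tested in edgeR 4.0.16 (R 4.3.3) with its quasi-likelihood test, TMM scaling and the default expression filter, which kept 218 miRNAs holding at least 99.62% of the reads of each library. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Maternal groups were compared over all 11 livers with no covariate. Effects within females and within males, and the difference between those effects, came from a model with a mean for each of the condition by sex groups. Males and females were compared in a model of condition and sex. Positive log2 values mean higher with maternal obesity, or higher in males for the sex comparison. Levels below are CPM of counts after TMM scaling, given as mean ± SD, except for pooled levels of miRNA lists. Those pooled levels, the hypoxia miRNA among them, are CPM without TMM scaling, so they are not on the scale of the levels of individual miRNAs. Depth and composition were compared with two-sided exact permutation tests over the 462 splits of the 11 livers, for which the smallest possible p is 0.00216.

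Before the data were examined, 24 lists of miRNAs (cell types, families, genomic clusters and metabolic roles) were fixed, together with the tests, most of the alternatives and the rule for naming miRNAs. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation. They were also tested with fry in its directional and mixed forms, and fry below means the directional form unless mixed is named. The rule names every miRNA past the threshold in the main comparison (up to 30), the 10 most abundant miRNAs, the 2 most abundant and the 2 lowest-p members of each list, up to 5 per direction in each sex comparison, and 3 predicted miRNAs by p. The ratio of 5p to 3p reads was tested with limma on log2((5p + 0.5)/(3p + 0.5)) at 41 loci with both arms tested. Alternatives covered RLE factors, total counts, leaving out the most abundant miRNA, other expression filters, summing the rows of a name, DESeq2 1.42.0, limma-voom, sex as a covariate, replicate number as a block, robust spread, the deposited normalised values, and each library left out in turn. Thinning every library to 247288 reads (10 draws), the summed let-7 members, the edgeR fits of the predicted table on recovered reads with TMM factors (its own or those of the known table), and its fits without TMM division or without matched or repeated entries, were added after the data were seen. The added edgeR fits on recovered reads called 16 and 18 entries, and the planned fits on them with RLE factors and in DESeq2 called 17 each.

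Libraries of control fetuses held 247288 to 319919 reads and those of fetuses of obese mothers 660569 to 767137. A count of 0 therefore allows up to 9.38 to 12.1 CPM in a control library and up to 3.91 to 4.54 CPM in a library of the other group (3 counts of the total, counting error only, since reads carried no molecular identifiers). On simulated counts with these depths (5 draws, a median of 224 miRNAs in the fit), the test of maternal groups recovered 49.5% of 1.5-fold, 90.7% of 2-fold and 99.0% of 3-fold changes. The corresponding shares were 18.0%, 63.6% and 98.0% within females (227 miRNAs), 19.2%, 55.7% and 96.0% within males (221 miRNAs), and 8.08%, 23.7% and 66.0% for the difference between sexes in the effect (221 miRNAs). Between males and females they were 38.1%, 90.7% and 100% (221 miRNAs). At the 41 loci of the arm ratio they were 8.00%, 55.0% and 90.0%, and for the predicted table (152 entries) 46.2%, 92.2% and 100%. Simulated miRNAs took the spread fitted to miRNAs of their abundance, and predicted entries the median of those spreads. No library was made to stand apart from its group, and many miRNAs or entries changed at the same time. The shares may therefore be higher than in the real data. No pair of libraries of a group agreed within counting noise (chi-square per degree of freedom of 14.0 to 190 over 25 pairs). This speaks only against the same library having been deposited again, and not for the independence of the samples.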

Results

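The study measured miRNA abundance in near-term fetal baboon liver and compared fetuses of obese mothers with fetuses of control mothers, in females and males. Reads on known miRNAs averaged 283321 ± 26580 per library (SD, n = 6) in controls and 713790 ± 42428 (SD, n = 5) with maternal obesity. Every library of the obese group was therefore deeper than every control library, by a ratio of means of 2.52 (exact permutation test, p = 0.00216, adjusted p = 0.00541 over 5 measures). The library numbers in the labels also separate the groups, running from 55 to 60 in controls and from 67 to 71 with maternal obesity, so no value within a batch could be had and a library batch cannot be told apart from maternal obesity. More miRNAs had reads with maternal obesity (471.2 ± 5.93 against 415.5 ± 10.2, exact permutation test, p = 0.00216, n = 5 and 6). After thinning to 247288 reads per library the numbers were 391.2 ± 9.76 and 402.7 ± 14.2 (exact permutation test, p = 0.173).

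**Figure D1:**
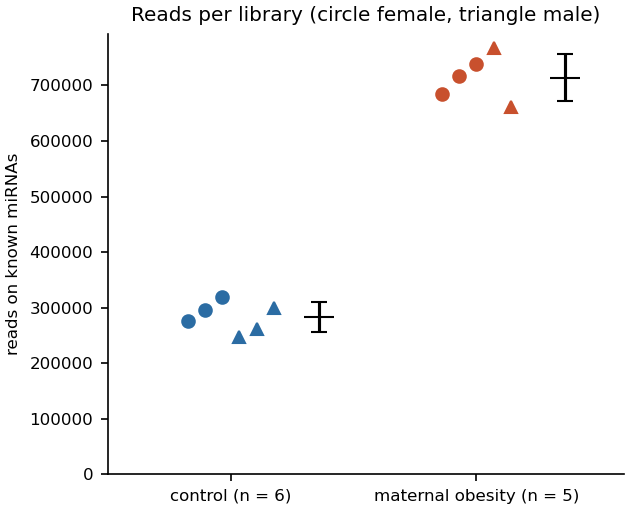
Reads on known miRNAs per library (y axis) for the 2 maternal groups (x axis), with circles for females, triangles for males and the mean ± SD beside each group. Control libraries lie between 247288 and 319919 reads and those of the obese group between 660569 and 767137.

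The liver profile was dominated by a few miRNAs in both groups. The most abundant was miR-192-5p, a liver and gut miRNA, with 22.8% ± 2.42 of reads in controls (n = 6) and 22.0% ± 1.11 with maternal obesity (n = 5, exact permutation test, p = 0.610). Next came miR-122-5p, the hepatocyte-specific miRNA, at 176125 ± 29816 and 145358 ± 31061 CPM, miR-143-3p, typical of smooth muscle and other mesenchymal cells, and miR-148a-3p, abundant in hepatocytes. The other 6 of the 10 most abundant were miR-26a-5p, miR-27b-3p, miR-10a-5p, miR-191-5p, miR-92a-3p and let-7f-5p. Together these 10 held 72.2% ± 2.10 of reads in controls and 72.0% ± 1.93 with maternal obesity (n = 6 and 5, exact permutation test, p = 0.877). Of the 10, let-7f-5p alone passed the threshold between the groups in the edgeR quasi-likelihood test. miR-143-3p stood at 78579 ± 6120 and 100964 ± 16833 CPM (log2 0.36, adjusted p = 0.0534).

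Livers of fetuses of obese mothers had lower let-7 family miRNAs and higher miRNAs of the miR-183 cluster than control livers, among 24 of 218 tested miRNAs past the threshold (10 higher and 14 lower, edgeR quasi-likelihood test, n = 5 and 6). The largest rise was in miR-183-5p, from 17.6 ± 9.84 to 57.9 ± 17.8 CPM (log2 1.69, SE 0.32, adjusted p = 0.00307). Its control level rested on 2 to 10 reads per library. Its cluster partner miR-182-5p rose from 141.1 ± 48.0 to 324 ± 121 CPM (log2 1.19, SE 0.26, adjusted p = 0.00648). miR-145-3p, the minor arm of a smooth muscle miRNA, rose from 45.7 ± 12.8 to 120 ± 30.8 CPM (log2 1.39, SE 0.23, adjusted p = 0.00229). The lowest adjusted p belonged to miR-99b-5p, which rose from 1371 ± 110 to 2322 ± 269 CPM (log2 0.76, SE 0.11, adjusted p = 0.00200). Among abundant miRNAs, miR-411-5p of the imprinted DLK1-DIO3 cluster rose from 7201 ± 920 to 12016 ± 1554 CPM (log2 0.74, SE 0.12, adjusted p = 0.00229). The other miRNAs that rose were miR-181c-5p (log2 1.10), miR-411-3p (0.78), miR-301a-3p (0.72), miR-215 (0.50) and the endothelial miR-126-5p (0.46).

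Of the 14 that were lower, 6 were let-7 family members. The other 8 included miR-885-5p, a liver-enriched miRNA, which fell from 157 ± 15.6 to 77.5 ± 20.4 CPM (log2 -1.01, SE 0.20, adjusted p = 0.00370). miR-378a-3p, encoded in the gene of the metabolic coactivator PGC-1beta, fell from 18339 ± 1753 to 12372 ± 2444 CPM (log2 -0.57, SE 0.13, adjusted p = 0.0122), together with its opposite arm miR-378a-5p (log2 -0.97) and the related miR-378i (-0.68). miR-675-3p, processed from the imprinted H19 transcript, stood at 62.6 ± 34.7 and 27.1 ± 7.67 CPM (log2 -1.20, adjusted p = 0.0310). miR-146a-5p, an inhibitor of inflammatory signalling, fell from 398 ± 82.5 to 251 ± 23.8 CPM (log2 -0.66, adjusted p = 0.0117), and miR-197-3p (-0.64) and miR-185-5p (-1.16) were also lower. For all 24, each of the 5 libraries of the obese group lay on the side of the control mean that the fold change gives. In 16 of the 24 the groups did not overlap at all. The 24 were chosen on the difference between these same libraries, so both counts were largely fixed by the choice. Over all 218 tested, 18 miRNAs had no overlap between the groups (7 higher and 11 lower), where chance gives 0.433% of miRNAs or 0.944 miRNAs. Of the 24, 12 stayed past the threshold under every alternative and with every library left out. Those of let-7f-5p, miR-126-5p, miR-301a-3p, miR-378i, miR-378a-5p, miR-411-3p, miR-675-3p and miR-185-5p held in only 2 to 5 of the 11 fits that left out 1 library.

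**Figure D2:**
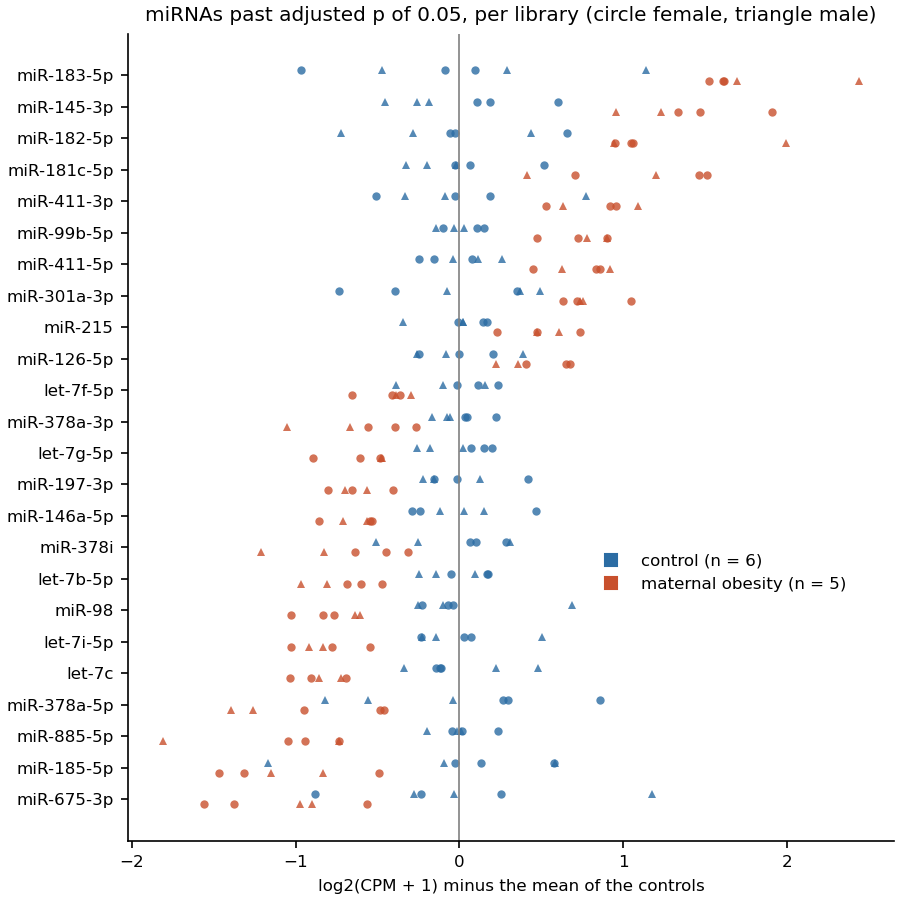
Each of the 24 miRNAs past the threshold (y axis) with log2(CPM + 1) minus the control mean (x axis) for 6 control libraries and 5 libraries of the obese group, circles female and triangles male. miR-183-5p (log2 1.69) and miR-145-3p (1.39) stand highest, and miR-675-3p (-1.20) and miR-185-5p (-1.16) lowest.

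The let-7 family, which rises as tissues differentiate and restrains LIN28 and insulin-PI3K signalling, was the only one of the 14 lists tested that passed camera at the preset correlation (adjusted p = 2.65e-06). The call was lost in camera with an estimated correlation (adjusted p = 0.0553 with an estimated correlation), and fry, which does not compare the list with other miRNAs, gave an adjusted p of 0.000640. Mixed fry, which asks whether members change in either direction, passed 6 of the 14 lists. Its adjusted p was 2.51e-06 for let-7, 0.0249 for miR-30, 0.0332 for insulin and glucose and 0.0405 for the DLK1-DIO3 cluster. The mesenchymal and leukocyte lists had 0.0432 each. Neither form of fry was run on other splits of the livers. All 11 tested members had negative log2 values, with a median of -0.51. 6 fell over all miRNAs tested and 8 adjusted over the list alone. let-7c fell from 2738 ± 598 to 1505 ± 144.9 CPM (log2 -0.86, SE 0.15, adjusted p = 0.00239), let-7i-5p from 3175 ± 668.5 to 1778 ± 227 CPM (log2 -0.84, SE 0.15) and let-7b-5p from 1037 ± 123.6 to 635 ± 81.9 CPM (log2 -0.71, SE 0.13). let-7f-5p, the most abundant member, fell from 22895 ± 3357 to 16985 ± 1529 CPM (log2 -0.43, SE 0.12), while let-7a-5p stood at 11070 ± 2513 and 8615 ± 671 CPM (log2 -0.36, adjusted p = 0.190). let-7g-5p (log2 -0.59) and miR-98 (-0.81) fell as well. Control replicate 4 had the highest let-7i-5p (4429 CPM) and miR-98 (2530 CPM) of the controls, and without it all 6 calls held. Over the 11 fits that left out 1 library, the let-7f-5p call held in only 2. Those of let-7c, let-7i-5p, let-7b-5p, let-7g-5p and miR-98 held in all 11. At least 1 list passed camera at the preset correlation in 93 of 100 splits of the 11 livers, the real one included. Near-identical members can share reads. The 9 members other than 3p arms, summed to 1 feature, were lower (log2 -0.47, SE 0.11, adjusted p = 0.0193 in edgeR).

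**Figure D3:**
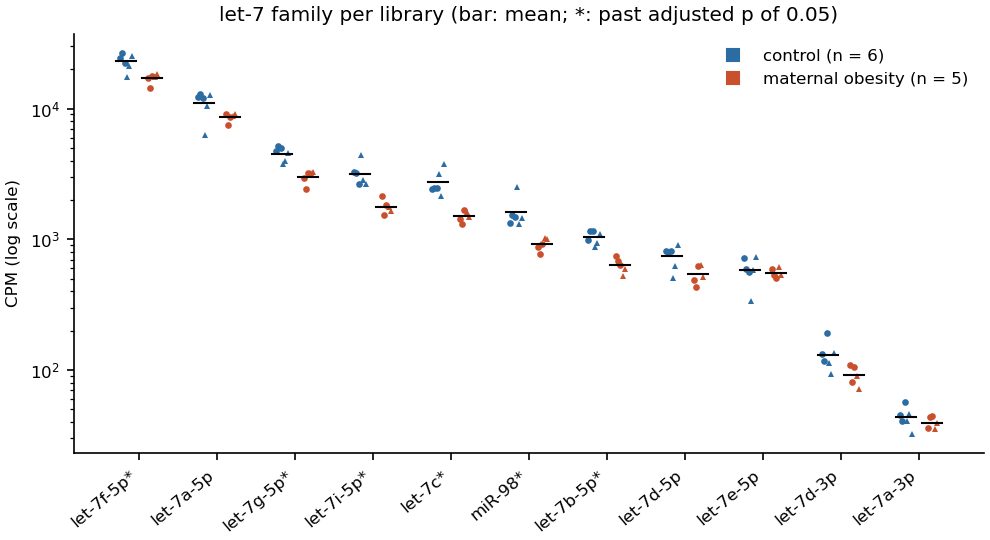
CPM on a log axis (y) of the 11 tested let-7 family members (x) in 6 control libraries and 5 libraries of the obese group, with bars at the means, circles for females and triangles for males, and an asterisk on members past the threshold. The mean of let-7c is 2738 CPM in controls and 1505 CPM with maternal obesity, and let-7e-5p has the smallest log2 change of the members (-0.08).

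Both tested members of the miR-183 cluster rose, as described, and both did so adjusted over the list alone. The pooled CPM of the cluster, without TMM scaling, was highest in replicate 5 of the obese group (612). Of the 9 tested hepatocyte miRNAs, 1 rose (miR-215, from 1791 ± 212 to 2542 ± 323.04 CPM) and 1 fell (miR-885-5p), and 7 did not pass, miR-192-5p (log2 -0.05) and miR-122-5p (-0.28) among them. The count adjusted over the list alone was the same, and camera gave the list an adjusted p of 0.966. Of the 25 tested miRNAs with roles in lipid metabolism, 3 fell (miR-378a-3p, miR-378a-5p and miR-185-5p, a regulator of cholesterol synthesis genes) and 22 did not pass, again with 3 adjusted over the list alone (camera adjusted p = 0.625). Of the 10 tested miRNAs linked to insulin and glucose, 1 rose (miR-126-5p, from 9663 ± 1773 to 13248 ± 1795 CPM), and adjusted over the list alone 2 did, miR-143-3p being the other (camera adjusted p = 0.233).

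Among lists for other cell types, the mesenchymal and stellate list had 1 of 9 members higher (miR-145-3p) and 2 adjusted over the list alone (camera adjusted p = 0.0744). Its pooled CPM, without TMM scaling, was 89006 ± 6318 in controls and 115650 ± 27526 with maternal obesity, highest in replicate 2 of the obese group (152208). miR-10b-5p of that list differed among libraries of each group, at 4817 ± 4489 and 8233 ± 9409 CPM (log2 0.77, adjusted p = 0.466), and its log2 value was -0.20 without replicate 2 of the obese group. The cluster of miR-143 and miR-145 had 1 of 3 members higher and 2 adjusted over the list alone (camera adjusted p = 0.0974), miR-145-5p standing at 271 ± 25.2 and 255 ± 82.5 CPM. Of the 2 arms of the endothelial miR-126, miR-126-5p rose, also adjusted over the list alone, and miR-126-3p did not pass (log2 0.17, adjusted p = 0.463). All 6 tested leukocyte miRNAs had negative log2 values (median -0.45). miR-146a-5p fell, and adjusted over the list alone miR-142-3p did too, at 69.8 ± 22.5 and 42.4 ± 8.23 CPM, while miR-142-5p did not pass (log2 -0.31). The leukocyte list did not pass camera (adjusted p = 0.0646) but passed fry, which asks whether its members move on balance in the same direction (adjusted p = 0.0275). How often other splits of the livers give such a pass in fry was not tested. None of the 4 erythroid miRNAs passed (median log2 -0.35), nor did any of them adjusted over the list alone, with miR-451a at 992 ± 403 and 675.6 ± 221.3 CPM, miR-486-5p at 12213 ± 3833 and 9965 ± 2974 CPM and miR-144-5p at log2 -0.40. The 4 biliary epithelial miRNAs had 0 past the threshold over all tested and 0 adjusted over the list alone, with miR-141-3p at 42.2 ± 28.3 and 110 ± 105.3 CPM, miR-200b-3p at log2 -0.26, miR-429 at -0.31 and miR-200a-3p at -0.07. Their median was -0.16 and their mean 0.19, which differ in sign. Reads of miR-141-3p, the only positive member, ran from 21 in replicate 5 to 184 in replicate 1 of the obese group.

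Of the 38 tested miRNAs of the imprinted DLK1-DIO3 cluster, both arms of miR-411 rose, 1 of them (miR-411-5p) adjusted over the list alone, and 36 did not pass, miR-127-3p among them (log2 0.21). The median was -0.01 and the camera adjusted p 0.260. In the miR-181 family, miR-181c-5p rose from 136.5 ± 29.7 to 292 ± 90.7 CPM while miR-181a-5p (log2 0.10) and miR-181b-5p (-0.07) did not pass, and adjusted over the list alone miR-181a-3p was lower as well (log2 -0.59; camera adjusted p = 0.816 for the list of 5). Of the 20 tested miRNAs of X-linked clusters, miR-98 fell, also adjusted over the list alone, and 19 did not pass, with miR-374b-5p at log2 -1.01 (adjusted p = 0.0585; camera adjusted p = 0.374). No member passed, over all tested or adjusted over the list alone, in the miR-17-92 and related clusters (11 tested, 9 negative, camera adjusted p = 0.303), with miR-25-3p at log2 -0.19, miR-106b-5p at -0.46 and miR-106b-3p at -0.40. The same held for the miR-30 family (9 tested, camera adjusted p = 0.745), with miR-30e-5p at 0.01, miR-30d-5p at 0.10, miR-30b-5p at -0.22 and miR-30c-1-3p at -0.50. It also held for miR-29a-3p (-0.26) and miR-29b-3p (0.21), for miR-10a-5p (0.18) and the already described miR-10b-5p, and for the islet miRNA miR-375 (0.30). The muscle, neural, placental and miR-34 family lists and the hypoxia miRNA miR-210 had no member that passed the expression filter. The pooled muscle CPM was 33.002 ± 18.5 in controls and 241 ± 431.4 with maternal obesity, with 1011 in replicate 2 of the obese group. This and the pooled values that follow in this paragraph, miR-210 included, are without TMM scaling. Pooled means in controls and with maternal obesity were 12.1 ± 9.99 and 10.2 ± 5.81 CPM for the neural list, 19.4 ± 33.5 and 4.59 ± 4.59 for the placental list, 44.2 ± 6.86 and 23.6 ± 6.77 for the miR-34 family, and 26.7 ± 13.8 and 37.6 ± 41.4 for miR-210. The miR-34 family ran from 32.6 to 52.6 CPM in controls and from 12.5 to 29.8 CPM in the obese group. It rested on only 9 to 22 reads per library. Single libraries carried some of the other means. Without control replicate 4 (28.3 CPM) the neural mean of controls was 8.85 CPM, below that of the obese group. Without control replicate 6 (87.1 CPM) the placental mean of controls was 5.91 CPM, and without replicate 2 of the obese group (111 CPM) its miR-210 mean was 19.1 CPM, below that of controls.

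In female fetuses, 13 miRNAs passed the threshold (6 higher and 7 lower, edgeR quasi-likelihood test, n = 3 and 3). miR-122-5p fell from 199331 ± 13005 to 126192 ± 21079 CPM (log2 -0.66, SE 0.14, adjusted p = 0.0320). let-7g-5p (log2 -0.79), let-7b-5p (-0.69), let-7f-5p (-0.58) and miR-378a-5p (-1.12) also fell, and miR-183-5p (1.87), miR-145-3p (1.29), miR-181c-5p (1.07), miR-411-5p (0.83) and miR-99b-5p (0.66) rose. In male fetuses, 9 passed (4 higher and 5 lower, n = 2 and 3). miR-182-5p rose from 125 ± 52.0 to 399 ± 197 CPM (log2 1.68, SE 0.36, adjusted p = 0.0293), with miR-183-5p (1.67), miR-145-3p (1.41) and miR-99b-5p (0.89). Of the 2 obese-group males, replicate 5 had 538 CPM of miR-182-5p, where the rest of the obese group averaged 270 ± 11.9. miR-378a-3p (log2 -0.75), let-7b-5p (-0.79), let-7c (-0.95), let-7i-5p (-0.96) and miR-432-5p (-1.20) fell, while miR-411-5p did not pass (log2 0.67, adjusted p = 0.0579). 5 miRNAs passed in both sexes with the same direction (miR-99b-5p, let-7c, let-7b-5p, miR-145-3p and miR-183-5p), where independent lists of these sizes would share 0.537. The 2 lists are not independent, since they came from 1 model with shared spread and scaling. Library numbers and depth also separate the groups in both sexes, so a batch could give the same overlap. These counts shifted with the libraries in the fit. Females gave 0 without control replicate 1, control replicate 3 or replicate 2 of the obese group, and 25 without control replicate 4, a male. Males gave 0 without any 1 of several libraries, female livers among them. Livers of the other sex enter a contrast only through the shared spread, filter and scaling. Fits on 1 sex alone gave 21 in females and 0 in males. With total counts in place of TMM the split was 8 higher and 3 lower in females and 3 higher and 8 lower in males, and with RLE factors, or with the most abundant miRNA left out, 6 higher and 5 lower in males.

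No miRNA passed the test of the difference between the effects in males and females (0 in edgeR, 0 in DESeq2 and 0 in limma-voom, 14 at an unadjusted p under 0.05, lowest adjusted p = 0.395; 11 passed in edgeR with no filter on low counts). All 24 miRNAs of the comparison over both sexes had the same sign in females and males. They were chosen on the effect over both sexes in these same livers, so this agreement was largely fixed by the choice. The test of the difference recovered only 23.7% of simulated 2-fold changes. The lowest p belonged to miR-122-5p, whose log2 change was -0.66 in females and 0.19 in males (152918 ± 20923 to 174105 ± 14688 CPM in males), a difference of 0.85 (SE 0.21, adjusted p = 0.395). miR-148a-3p had a difference of 0.65, miR-191-5p 0.73, miR-375 0.71 and miR-320a 0.64, and on the other side stood miR-144-5p (-1.49), miR-195-5p (-1.26), miR-451a (-1.15), miR-432-5p (-0.94) and miR-381 (-0.52), none past the threshold.

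**Figure D4:**
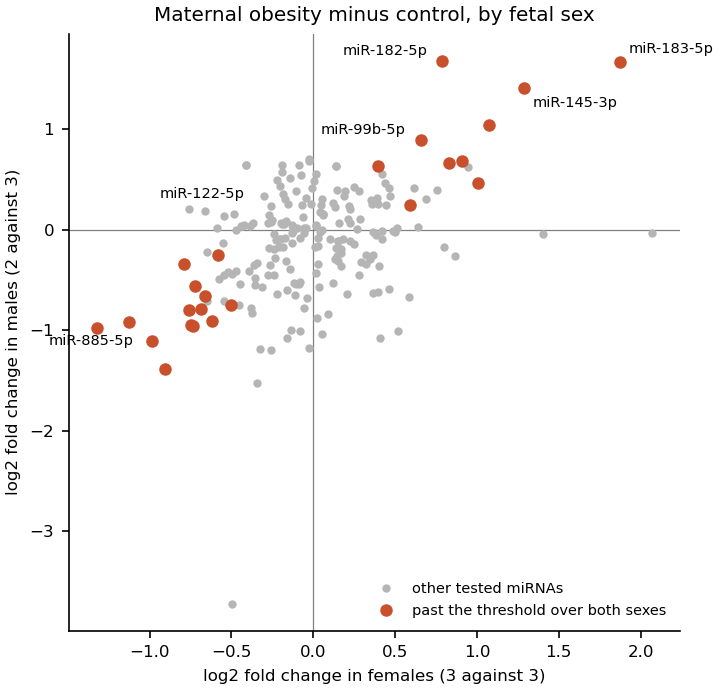
Log2 fold change of maternal obesity against control in females (x axis, 3 against 3 livers) and males (y axis, 2 against 3 livers), with 1 point per tested miRNA and larger points for the 24 past the threshold over both sexes. All 24 lie in the quadrants of the same sign, from miR-183-5p (1.87 and 1.67) down, while miR-122-5p lies at -0.66 and 0.19. Choosing the 24 on the effect over both sexes largely fixed this.

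Between males and females, no miRNA passed (0 in edgeR, 0 in DESeq2 and 0 in limma-voom, 22 at an unadjusted p under 0.05, lowest adjusted p = 0.196, n = 5 and 6; 6 passed in edgeR with no filter on low counts). The lowest p values belonged to members of the miR-378 family. miR-378a-5p stood at 79.1 ± 36.9 CPM in females and 45.8 ± 18.5 in males (log2 -0.84, SE 0.21, adjusted p = 0.196) and miR-378c at 443 ± 70.9 and 301 ± 66.3 CPM (log2 -0.60, SE 0.16). miR-195-5p (log2 -0.92), miR-574-5p (-0.75) and miR-214-3p (-0.59) had lower values in males, and miR-19b-3p (0.96), miR-19a-3p (0.67), miR-183-5p (0.59), miR-128 (0.55) and miR-744-5p (0.41) higher values, without passing. Control replicate 4, a male, held the highest miR-19b-3p (5052 CPM) and miR-19a-3p (655.4 CPM) of the controls.

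In the table of predicted miRNAs, 132 entries matched the counts of a known miRNA within 5%. Of the 87 matched and 56 other entries tested with limma on log2(RPM + 1), 17 passed the threshold (8 higher and 9 lower, n = 5 and 6), and 6 did when the matched entries were left out. Of the 17, 12 matched a known miRNA and 10 matched one of the 24 already described. Some entries held identical values, among them 2 of the 8 higher, both matched to miR-16-5p. With identical entries counted 1 time, 15 passed (7 higher and 8 lower). The lowest p belonged to an entry on human chromosome 19 (chr19_22400) that rose from 1213 ± 71.5 to 2090 ± 198 RPM (log2 0.81, SE 0.11, adjusted p = 0.000556) and held the reads of miR-99b-5p. The next, chr21_23652, fell from 3223 ± 679 to 1850 ± 142.6 RPM (log2 -0.75, adjusted p = 0.00141), and chr14_18262 rose from 3712 ± 658 to 6277 ± 1068 RPM (log2 0.78, adjusted p = 0.00238). These and the other 3 of the 5 without a match are not identified here, because no sequences were used. The other 3 were chr5_8057 (log2 0.51), chr1_559 (-0.61) and chr5_8061 (-0.58), named after their values were seen. By number, chr21_23652 stood between entries matched to miR-99a-5p and miR-125b-5p, and chr14_18262 after 1 matched to miR-379-5p. Missing the 5% match does not make an entry separate, so these 5 may repeat known miRNAs, some of the 24 among them.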

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

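The test of miR-4485 was chosen after its values had been seen; thinning was chosen after the data were seen, and the separate reading of the neural list after its values were seen. In 25 sets of values within a group, the highest or lowest library lay far from the rest for the range of its group, where chance gives about 1 in 20 of the sets tested, or 11. Of the 25, 10 were in control replicate 4, 5 each in replicates 2 and 5 of the obese group, 2 each in control replicates 1 and 3, and 1 in control replicate 6.

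Control replicate 4 had 5052 CPM of miR-19b-3p against 852 ± 69.4 in the other controls (SD, n = 5) and 655.4 CPM of its cluster partner miR-19a-3p against 189 ± 10.4. It also had the highest let-7i-5p (4429 CPM, others 2924 ± 294), miR-98 (2530 CPM, others 1428 ± 95.1), miR-127-3p (24136 CPM, others 15334 ± 1525), miR-374b-5p (165.7 CPM, others 53.4 ± 10.6), miR-432-5p (280 CPM, others 139 ± 15.2) and miR-4485 (357 CPM, others 46.4 ± 39.6). Its miR-210, without TMM scaling, was also the highest of the controls (52.6 CPM, others 21.6 ± 6.17). Lower there, without a test, were miR-151a-5p (751 CPM, others 3321 ± 455), miR-122-3p (526.5 CPM, others 1997 ± 394) and miR-125b-5p (608 CPM, others 2038 ± 189).

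Its mean correlation with the other libraries was 0.949, against 0.978 ± 0.00214 for the other controls, and 43 miRNAs lay over 2-fold from the mean of its group, against 3 to 8 in each other library. Its depth was the lowest, but with every library thinned to that depth its correlation was still 0.0253 below the lowest of the others, which argues against low depth. The muscle, pancreatic and placental lists were not highest there (0 of 3 at more than 2 times every other library). For muscle and pancreas this argues against cells of those tissues. The placental list held only 0 to 26 reads per library, too few to decide, so placental cells stay open. The neural list was highest there, at 28.3 CPM and 1.69 times the next library, but held at most 12 reads in any library, so neural cells stay open. A difference in the handling of this sample and a difference of this animal stay open and were not tested.

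In the obese group, replicate 5 had the highest miR-183-5p (89.5 CPM, others 49.97 ± 2.40), miR-182-5p (538 CPM, others 270 ± 11.9) and miR-142-3p (56.5 CPM, others 38.9 ± 2.80). It also had the highest pooled miR-183 cluster, without TMM scaling (612 CPM, others 326 ± 19.2), and the lowest miR-181a-3p (31.4 CPM, others 46.2 ± 1.81). Without TMM scaling, replicate 2 had 1011 CPM of pooled muscle miRNAs against 48.7 ± 31.6 in the others and 111 CPM of miR-210 against 19.1 ± 3.37. The next highest muscle value of any library was 92.1 CPM, in replicate 1 of the obese group. Muscle cells in the sample of replicate 2 were not tested and stay open. With TMM scaling, replicate 2 had the highest miR-301a-3p (257 CPM, others 204 ± 7.45), and the lowest let-7a-5p (7471 CPM, others 8901 ± 233) and miR-30e-5p (10411 CPM, others 12973 ± 326). Control replicate 1 had 13879 CPM of miR-10b-5p against 3005 ± 747 and 11119 CPM of miR-30d-5p against 9385 ± 251. Control replicate 3 had 303 CPM of miR-29a-3p against 193 ± 5.37 and 390 CPM of pooled let-7 3p arms against 248 ± 14.3, both after TMM scaling. Control replicate 6 had 87.1 CPM of pooled placental miRNAs, without TMM scaling, against 5.91 ± 5.51.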

How the results depend on the processing

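Thinning, the fits without matched or repeated entries and the fit of undivided RPM were chosen after the data were seen. Between maternal groups, 24 miRNAs became 16 to 29 under every setting but the replicate block (15) and 16 to 26 with 1 library left out. Of 1521 values of named miRNAs and settings, 1394 kept their side of the threshold (32 of them, all uncalled, with the other sign), 114 lost the call, 13 gained it and 0 called values changed sign. In females, 13 became 6 at a mean CPM of at least 10, 5 with the rows of a name summed and 21 in females only, and 0 to 25 with 1 library left out: 0 without control replicates 1 or 3 or obese replicate 2, 1 without obese replicate 1, 2 without control replicate 2, 7 without control replicate 5, 8 without obese replicates 4 or 5, and 25 without control replicate 4. In males, 9 became 27 with no low-count filter, 18 in DESeq2 and 0 in males only, and 0 to 13 with 1 library left out: 0 without control replicates 1, 2, 3 or 6 or obese replicates 2, 3 or 5, 2 without obese replicates 1 or 4, and 3 without control replicate 4. Where 1 obese male remained, it was assumed to vary like the other groups. With no low-count filter, the interaction went from 0 to 11 and the sex comparison from 0 to 6; with 1 library left out both stayed at 0. Predicted entries went from 17 to 6 without matched entries, to 15 with identical entries counted 1 time, to 16 undivided, and to 13 to 21 with 1 library left out. Lists went from 1 to 0 with an estimated correlation and to 1 to 4 with 1 library left out: 4 without obese replicate 5, 3 without control replicate 1 or obese replicates 1, 3 or 4, and 2 without control replicates 2 or 4. Loci with a changed arm ratio went from 1 to 2 with a pseudocount of 5 and to 1 to 3 with 1 library left out (3 without control replicate 4). The replicate numbers did not pair the samples (2 of 5 correlations over 0.1, own number the best partner for 2 of 5 controls and 1 of 5 obese-group livers); with that block the calls were 15 of 24 miRNAs, 2 lists and 12 of 17 predicted entries. Apart from settings that use fewer samples or entries, the cause was not tested. Simulated at these depths and group sizes, 2-fold changes were recovered in 23.7% of cases in the sex by obesity test and 90.7% between maternal groups; the part of depth in this was not tested.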

Other observations

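The tests of opposite arms, of any batch, and of the let-7 list over other splits were chosen after the results were seen, and thinning and the let-7 3p fits without 1 library were chosen after the data were seen. The use of the arms of miR-145, a smooth muscle miRNA, differed between groups. Its log2 ratio of 5p to 3p reads was 2.56 ± 0.31 in controls (SD, n = 6) and 1.06 ± 0.27 with maternal obesity (n = 5), a difference of -1.50 (SE 0.18, adjusted p = 7.96e-05 in limma). It was the only 1 of 41 loci past the threshold, with 4 at an unadjusted p under 0.05. A count of 1 locus or more came up in 7 of 100 splits of the livers, highest other 1, so chance cannot be excluded for the count.

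Across the 41 loci with both arms tested, 27 had the same sign of change in both arms. Pearson's r across loci was 0.39 (permutation p = 0.0116) and Spearman's rho 0.47 (permutation p = 0.00247); loci are not independent replicates.

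The 24 miRNAs past the threshold with maternal obesity exceeded every other drawn split of the livers (1 of 100 splits with as many, highest other 6), which argues against chance. With all libraries thinned to the lowest depth, a median of 18.5 of the 24 stayed past the threshold, which argues against depth as the whole cause. A library batch cannot be told apart from maternal obesity, since 0 control libraries lay within the library numbers or depths of the other group. A batch that biased each sequence on its own stays open as well: both arms moved the same way at 3 of 4 loci with a called arm (one-sided exact binomial test, p = 0.313, smallest possible 0.0625). An effect of maternal obesity is a hypothesis that may account for the calls.

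For the lower let-7 family, 6 of 6 called members stayed past the threshold after thinning (median of draws) and 6 of 6 without control replicate 4, which argues against depth or control replicate 4 alone. As a list it is weaker: any list had a camera p as small as that of let-7 (1.89e-07) in 22 of 100 splits, with 6.75e-16 the lowest in another, so chance cannot be excluded for the list test. Reads of 1 member counted at near-identical members may also contribute. The pooled let-7 3p arms, whose sequences differ, had a log2 ratio of -0.26 (exact permutation p = 0.0952, n = 5 and 6), and -0.15 without control replicate 3, which leaves this open. An effect of maternal obesity and a batch stay open too.

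Of the other counts, the 17 predicted entries came up in 1 of 100 splits (highest other 3), which argues against chance. Since 12 of the 17 matched a known miRNA, this count is largely not separate from that of the known miRNAs. Entries without a match may repeat known miRNAs too, and were not tested over splits on their own. Lists past the threshold came up as often in 93 of 100 splits (real 1, highest other 6), so chance cannot be excluded for their number. For the 13 miRNAs in females, the 10 possible splits are too few for a share under 0.05 (1 of 10 with as many, highest other 3). For the 0 miRNAs between males and females, 100 of 100 splits gave as many, which decides nothing, since no split can give fewer. The highest other gave 50, in a split that, with condition in the model, set control replicate 4 alone against the other 5 controls, so that count describes that library.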
